A study of Pseudomonas aeruginosa with 4 samples.

How the data were processed

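RNA was sequenced from 4 planktonic cultures of Pseudomonas aeruginosa strain UCBPP-PA14 (PA14), a virulent clinical isolate that serves as a common laboratory reference. Per the labels' protocols, cells were stabilised in an RNA-preserving buffer and RNA was isolated on columns. Messenger RNA was then enriched with MICROBExpress, a kit that captures and removes ribosomal RNA. The RNA was fragmented and ligated to RNA adapters that carried a sample barcode, and the amplified cDNA was read on an Illumina Genome Analyzer IIx. The aligner, the counting program, the genome build, the annotation and the use of strand are not given in the sources used here. How reads matching more than 1 place were treated is not given either, so genes that overlap, or that have a near-identical copy, hold uncertain counts.

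The authors deposited 1 table of raw read counts per feature, with 1 column per library and no scaling. The values were whole numbers and the column totals differed between libraries, as raw counts do. The column names were the sample titles, and 0 other columns of sample values were present. The table held 6014 features, of which 15 had no read in any library. Of these features, 5965 carried a PA14 locus tag and 49 carried an identifier in the style of strain PAO1, the other common reference strain. Gene names came from a RefSeq table of the PAO1 assembly ASM676v1. It matched 34 of the 6014 identifiers and 0 of the 5965 PA14 tags. Of the 15 PAO1-style identifiers that did not match, 13 named a pair of neighbouring loci. Only 12 matched features had a gene symbol. The PA14 genes are therefore not named here, and no coordinates are given because the reference is of another strain.

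The test used edgeR's quasi-likelihood F test on the counts as deposited, with edgeR 4.0.16 in R 4.3.3. Scaling used the trimmed mean of M values (TMM). Low features were removed with filterByExpr at its defaults, a minimum count of 10 in enough libraries and a minimum total of 15, which left 4300 features. Groups were taken from the sample titles, with 2 control and 2 ciprofloxacin libraries. The model held the treatment only, with 2 residual degrees of freedom, and tests were two-sided. Adjusted p-values are Benjamini-Hochberg values over the 4300 features, and the threshold was 0.05. Fold changes are log2 of ciprofloxacin over control. Their standard errors were taken as the fold change divided by the square root of its F statistic. Normalised counts are CPM values of the TMM-scaled library. The 6 features that the reference calls tRNA (5) or rRNA (1, the signal recognition particle RNA gene ffs) were left out of the library sizes and the test. They held between 0.00476% and 0.0520% of a library's reads. Other rRNA and tRNA genes bear PA14 tags and could not be recognised by name, so they stayed in.

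The test, its threshold, the rule for naming genes and 33 gene lists (DNA damage response, bacteriocins, efflux, motility, virulence and others) were fixed before the data were examined. The naming rule took genes with adjusted p below 0.05, a mean of at least 10 CPM and groups that did not overlap, ranked by fold change. It allowed at most 2 identifiers per direction if the reference did not name them, which was the case. The lists matched 0 of the named features, so the planned list tests (camera and fry) were not run. Features with a symbol in the reference are reported whatever their values. Other summaries were added after the data were seen, namely runs of neighbouring tags, the share of reads in the 8 most abundant features and the trend of fold changes along the tag order. A run is a stretch of consecutive tested PA14 tags, in table order, that all passed the threshold in one direction. Locus tags are by convention numbered along the chromosome. Runs were compared with 10000 random placements of the passing features among the tested tags. The trend is the slope of the log2 fold change on the distance from the middle of the order of the 5965 tags (0 at the middle, 1 at either end), without the 60 genes that rose. It was compared with 10000 shuffles of 20 equal stretches of the order.

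Shares of reads carry 95% Wilson intervals. Reads have no molecular identifiers, so the intervals cover counting error only. Nothing in the labels says that same-group libraries came from separate pre-cultures, so p-values measure the spread between these libraries, which may be technical. The replicates of a group were distinct libraries, since their counts differed by a chi-square statistic of 130.5 times its degrees of freedom for control and 46.4 times for ciprofloxacin.

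The procedure was tested on simulated data. In 10 simulations of 4300 features, 200 features were changed each time. The test recovered 50.0% of 4-fold rises and 54.0% of 4-fold falls. It recovered 88.8% of 8-fold rises and 93.2% of 8-fold falls. Of 2-fold changes it recovered 2.0% of rises and 6.4% of falls. False calls were 4.87% of all calls. Alternatives were other scalings, other filters on low counts, a replicate term, leaving out each library, keeping the tRNA and rRNA features, DESeq2 1.42.0, limma-voom (limma 3.58.1), a test against a 1.5-fold change, and removal of the 8 most abundant features.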

Results

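Transcript levels were measured by RNA sequencing in cultures of P. aeruginosa PA14 grown in lysogeny broth at 37 °C, with and without ciprofloxacin. Ciprofloxacin is a fluoroquinolone that traps DNA gyrase and topoisomerase on DNA and so damages it. Cultures of 10 mL were started from a pre-culture at an optical density of 0.02. Treated cultures received a concentration below the inhibitory level at an optical density of 0.5 and were exposed for 3 h. The labels give no concentration. Controls carried the same 3 h label. Each group held 2 libraries. The total count was 5606952 and 2965359 reads for control replicates 1 and 2, and 2568569 and 2968369 for ciprofloxacin replicates 1 and 2. Reads fell on 5797, 5668, 5929 and 5690 of the 6014 features in these libraries, in the same order. The series concerns how environments change mRNA and protein levels, and the comparison asks which transcripts differ after exposure to the drug.

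A set of 8 features took most of the control reads and a smaller share of the treated reads. They took 84.2% of the reads in control replicate 1 (Wilson interval 84.1% to 84.2%) and 63.6% in control replicate 2 (63.6% to 63.7%). They took 39.5% in ciprofloxacin replicate 1 (39.5% to 39.6%) and 51.1% in ciprofloxacin replicate 2 (51.1% to 51.2%). The means were 73.9% ± 14.5 for control and 45.3% ± 8.22 for ciprofloxacin (SD, n = 2), a difference of -28.6 percentage points. Both treated libraries lay below both controls, which an exact two-sided permutation test of 2 against 2 gives at p = 0.333, the smallest value this design allows. The 8 features fell into 2 sets of 4 with nearly equal counts. Within a set, counts varied by a coefficient of variation of at most 4.69% in any library, so that reads of the members may not be separable. The 8 are not named here, and rRNA genes with PA14 tags stayed in, so they may include rRNA left by the enrichment. The difference in share may then reflect rRNA removal and not a change in transcripts, which was not tested. The fitted log2 fold changes of the 8 features lay between -1.73 and -1.50. None passed the threshold by edgeR's quasi-likelihood test (lowest Benjamini-Hochberg adjusted p = 0.9997). Outside these features the depth was 888014 and 1078601 reads for the controls and 1553618 and 1450249 reads for the treated libraries.

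After ciprofloxacin 60 of the 4300 tested features rose and 0 fell by edgeR's quasi-likelihood test. The 60 rose by 2.30 to 5.77 on the log2 scale, with a median of 3.98 or about 15.8-fold. In all 60, both treated libraries exceeded both controls; over all tested features the groups did not overlap in 29.2%, where chance gives 33.3%. The lowest adjusted p among features with lower values was 0.246. At an unadjusted p below 0.05 there were 225 of the 4300 features, 182 with higher and 43 with lower values. The total of 225 is close to what this cutoff would pass without any effect. Its split of 182 higher and 43 lower was uneven, however, and 60 of the higher passed the adjusted threshold. The total alone therefore does not show that these features are noise. DESeq2 called 77 higher and 1 lower, and limma-voom 56 higher and 0 lower. Over 14 alternative settings between 0 and 52 features were called lower. The 52 came from a fit with a replicate term, which called 170 higher, though the labels do not pair the samples. Without ciprofloxacin replicate 1 there were 0 calls, at 107 features with unadjusted p below 0.05. Without control replicate 2 there were 84 features higher and 25 lower.

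In the main fit, most of the features that rose stood in a single stretch. This did not hold in fits that called many more features higher, such as the 87 with total count alone. An uninterrupted run of 34 consecutive locus tags rose together, by 3.22 to 4.83 on the log2 scale (median 4.16, about 17.9-fold), with a highest adjusted p of 0.0484. In each of the 34 genes both treated libraries exceeded both controls. The run's share of the reads outside the 8 most abundant features was 0.777% ± 0.215 in control and 12.5% ± 2.71 with ciprofloxacin (SD, n = 2), a ratio of 16.1. By library it was 0.625% and 0.929% in control replicates 1 and 2, and 14.4% and 10.6% in ciprofloxacin replicates 1 and 2. Over 10000 random placements of the features that rose, the longest run had 3 members, and the permutation p was 1e-04, the smallest these placements can give. The stretch was broken by genes near the threshold in some settings: its longest unbroken part was 21 genes with size factors of the DESeq2 kind, where 33 of the 34 were called. The calls of this run were lost without ciprofloxacin replicate 1, where its median log2 fold change was 3.96 and all 34 genes had an unadjusted p below 0.05.

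**Figure D1:**
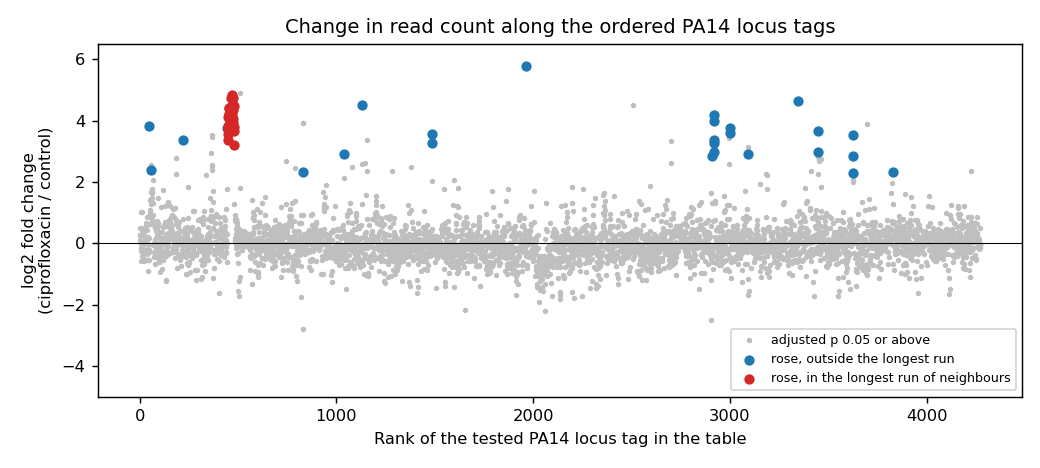
Log2 fold change of ciprofloxacin over control (vertical axis) for each tested PA14 locus tag, by its rank in the table (horizontal axis); each point is a gene, with genes of adjusted p below 0.05 in blue or, in the longest run, red. The 34 red points of the run stand together between 3.22 and 4.83, and the blue points are scattered along the axis, 1 of them beside the run.

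The genes with the largest fold change under the naming rule both lay in this run. PA14_08190 rose from 5.20 ± 2.14 to 149.1 ± 17.4 CPM (SD, n = 2 per group), a log2 fold change of 4.83 with a standard error of 0.531 and an adjusted p of 0.00685 by edgeR's quasi-likelihood test. Its counts were 20 and 11 reads in the controls and 682 and 456 in the treated libraries. PA14_08280 rose from 30.2 ± 12.8 to 808.1 ± 199 CPM, a log2 fold change of 4.74 with a standard error of 0.624 and the same adjusted p. Its counts were 63 and 117 reads in the controls and 4009 and 2226 in the treated libraries. Without ciprofloxacin replicate 1 their log2 fold changes were 4.71 and 4.47 and the adjusted p was 0.324 for each.

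The other 26 genes that rose were spread over 17 further places. They formed further runs of 5, 3, 2, 2 and 2 neighbours and 12 single genes, and rose by 2.30 to 5.77 on the log2 scale with a median of 3.37. Together they took 0.190% ± 0.0360 of the reads outside the 8 most abundant features in control and 2.23% ± 0.00707 with ciprofloxacin (SD, n = 2), a ratio of 11.7. In all, 48 of the 60 genes had an immediate neighbour that also rose, against at most 10 in any random placement (permutation p = 1e-04, again the smallest possible). Random placement treats neighbouring genes as independent, so this shows clustering and not its cause.

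**Figure D2:**
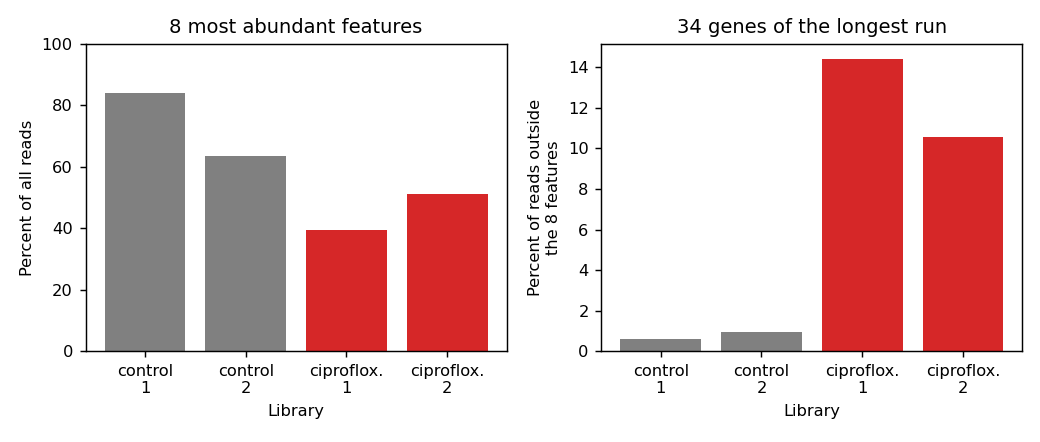
Percent of all reads in the 8 most abundant features (left) and percent of the remaining reads in the 34 genes of the longest run (right), with 1 bar per library, controls grey and ciprofloxacin red. The 8 features held 84.2% and 63.6% in the controls and 39.5% and 51.1% in the treated libraries, and the run held 0.625% and 0.929% against 14.4% and 10.6%.

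Among the features that the reference names, mostly small regulatory and housekeeping RNAs, no change passed the test. Of 11 tested features with a gene symbol, 0 passed by edgeR's quasi-likelihood test over all features, and 0 passed when adjusted over the list alone (lowest adjusted p = 0.593). Their lowest unadjusted p was 0.103, and DESeq2 and limma-voom also called 0 of them; prrF1 alone was called elsewhere, in 2 of 14 alternatives. With TMM scaling 8 had lower and 3 higher values with ciprofloxacin, but 2 lower and 9 higher when libraries were scaled by total count alone, so no direction is given for the group. The transfer-messenger RNA ssrA, which rescues stalled ribosomes, had 20290 ± 4069 CPM in control and 8663 ± 467.2 with ciprofloxacin (SD, n = 2). The RNA subunit of RNase P, rnpB, had 7621 ± 3336 and 4572 ± 3247 CPM. The carbon catabolite RNA crcZ, which binds the RNA chaperone Hfq, had 6566 ± 1197 and 4804 ± 476.4 CPM.

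Several of the regulatory RNAs differed more within a group than between groups. The iron-responsive RNA prrF1 had 117.4 and 13.4 CPM in the 2 controls and 210.1 and 36.6 CPM in the treated libraries. Its log2 fold change was 0.92 with a standard error of 0.934. It was 3.15 without control replicate 1, where its adjusted p was 0.00969, and -0.83 without ciprofloxacin replicate 1, where it was 0.998. Its near-identical neighbour prrF2 had 5.20 ± 6.40 and 3.33 ± 1.31 CPM (SD, n = 2), and reads may be shared between the pair. The RNA rsmZ, which sequesters the translational repressor RsmA, had 967.6 and 258.4 CPM in the controls and 445.1 and 545.3 CPM in the treated libraries. The RNA polymerase regulator ssrS had 74.3 ± 33.9 CPM in control and 117.8 ± 103 with ciprofloxacin (SD, n = 2). The remaining RNAs rgsA, phrS and amiL had log2 fold changes of -1.23, -0.41 and -0.64, with standard errors of 0.683, 0.496 and 0.555. The controls of rgsA differed, with 398.8 and 76.8 CPM, against 113.6 and 89.4 CPM in the treated libraries. Its log2 fold change was 0.37 without control replicate 1 and -1.98 without control replicate 2. The protein-coding ccoQ2, a subunit of a terminal oxidase, had 29.0 ± 11.1 and 38.0 ± 12.5 CPM.

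**Figure D3:**
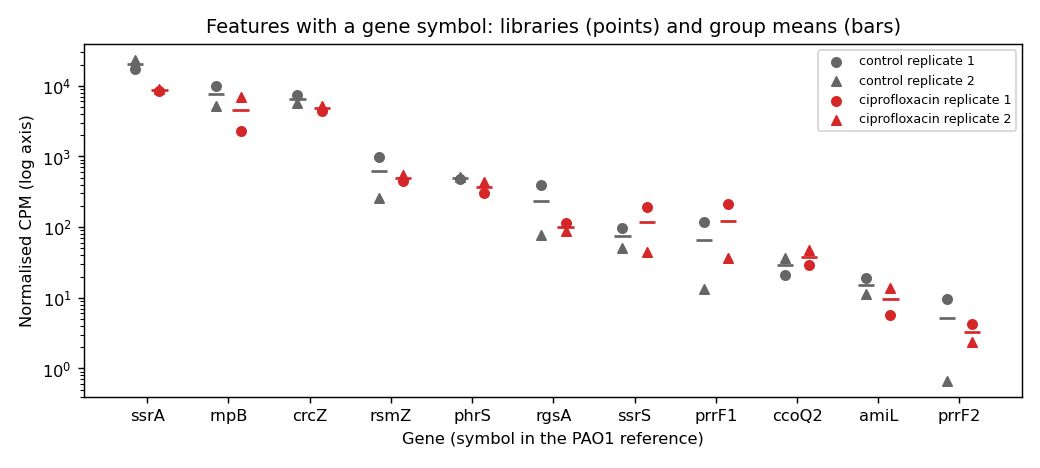
Normalised CPM on a log axis for the 11 tested features with a gene symbol, by gene on the horizontal axis; points are libraries (circles replicate 1, triangles replicate 2), short bars are group means, controls grey and ciprofloxacin red. For prrF1 the libraries of a group lie farther apart (117.4 and 13.4 CPM in control) than the group means (65.4 and 123.4 CPM).

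Of the 27 tested features without a PA14 tag, 0 passed the threshold and 2 had an unadjusted p below 0.05. These were named after their values were seen. The non-coding RNA PA1324.1 had 79.5 CPM in control replicate 1 and 7.71 in control replicate 2, against 8.99 and 8.10 in the treated libraries. Its log2 fold change of -2.34 (standard error 0.836, adjusted p = 0.597 by edgeR's quasi-likelihood test) became 0.12 without control replicate 1 (adjusted p = 0.998) and -3.21 without control replicate 2 (adjusted p = 8.05e-05); it passed in 2 of 14 alternatives. The non-coding RNA PA5181.1 had 6.87 ± 2.61 CPM in control and 17.8 ± 2.65 with ciprofloxacin (SD, n = 2), a log2 fold change of 1.37 with a standard error of 0.497 and an adjusted p of 0.630; it passed in 1 of 14 alternatives.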

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

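The tRNA gene PA1796.2 was outside the test, as were the other features that the reference calls tRNA or rRNA, and it drew attention because both treated libraries lay above both controls. It had 6.37 and 4.02 CPM in the controls and 14.2 and 7.80 CPM in the ciprofloxacin libraries, from 19, 12, 60 and 26 reads. When these features were kept in the fit its log2 fold change was 1.08, with an adjusted p of 0.9997 and an unadjusted p of 0.0794 by edgeR's quasi-likelihood test.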

How the results depend on the processing

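Removal of the 8 most abundant features, the run summary and the leave-one-out values of the 8 features' share were chosen after seeing the data. The main count was 60 features, all higher. It was 55 with size factors of the DESeq2 kind, 81 (1 of them lower) without a filter on low counts, 58 at a mean of at least 10 CPM, 57 with tRNA and rRNA kept, 78 (1 lower) with DESeq2, 56 with limma-voom, 49 against a 1.5-fold change and 58 without the 8 most abundant features, and of the 60 genes 55, 60, 57, 57, 60, 54, 49 and 58 were called there. With total count alone it was 87, and the median log2 fold change of all features moved from -0.01 to 0.84. Leaving out a library gave between 0 and 109 calls; the 0 came without ciprofloxacin replicate 1 and the 109 without control replicate 2. The run of 34 genes kept 33 or 34 calls under each of these settings except without ciprofloxacin replicate 1, so that leaving out a library gave between 0 and 34; bridging 1 uncalled gene made it 35 called genes. Where 33 were called, the missing gene could break the stretch: the longest unbroken part had 21 genes with size factors of the DESeq2 kind, with tRNA and rRNA kept, against a 1.5-fold change and without the 8 most abundant features, 23 without ciprofloxacin replicate 2 and 33 without control replicate 1. Wherever a library was left out, the single library of its group is assumed to vary like the other group, and the cause of the lost calls was not tested. With a replicate block, which used the number in the titles, there were 222 calls, 170 higher and 52 lower, and all 60 were among the higher; prrF1, PA1324.1 (log2 fold change -1.84) and PA5181.1 passed there too. The deviations of same-numbered libraries correlated at 0.51 across genes, but nothing in the labels says that a number marks a shared culture or day, and 2 pairs cannot settle it. Log2 CPM values correlated at 0.95 between control replicate 2 and ciprofloxacin replicate 2, and at 0.885 between the replicate 1 libraries. Within groups the correlation was 0.916 for control and 0.933 for ciprofloxacin. The difference in the 8 features' share lay between -38.8 and -18.3 percentage points when a library was left out. PA14_08190 and PA14_08280 lost significance in 1 of 14 alternatives each, without ciprofloxacin replicate 1. Not run were the list tests and the removal of the pyocin list from the scaling, since the lists matched no feature, and the pseudocounts, which are for normalised values only. With these depths, 2 libraries per group and the spread between them, 2.0% of simulated 2-fold rises were recovered; the share of this due to depth was not separated.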

Other observations

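Apart from the called genes, fold changes followed a gradient along the chromosome order of the locus tags. Genes at either end of the order had higher values with ciprofloxacin than genes in its middle. Over 4213 genes, those that rose being left out, the slope from the middle to the ends was 0.356 on the log2 scale (standard error 0.032 across genes, which are not independent replicates), a 1.28-fold difference. Split into 20 stretches, the median log2 fold change was 0.15 in the first, -0.22 in the tenth, -0.19 in the eleventh and 0.10 in the last. Gene by gene the trend was weak, with a Spearman correlation of 0.19. With each library set against the mean of the 4, the slope was -0.158 and -0.191 in the control libraries. It was 0.171 and 0.179 in the ciprofloxacin libraries. These deviations from a shared mean balance each other by construction, so they are not 4 separate results. Across 15 settings the slope lay between 0.332 and 0.407, and no single library carried it.

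Of the tests in the paragraphs that follow, those of the simulated falls, the random placements, the shuffled stretches and the DNA carry-over were set before their results were seen, and the others after.

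A chance order of genes is argued against as the reason for this gradient, since shuffles of the 20 stretches gave at most 0.314 (permutation p = 1e-04, the smallest they can give). These shuffles speak to the order of genes and not to a difference between treatments. For that, an exact permutation test of 2 against 2 libraries cannot give p below 0.333. The slope was 0.27 (standard error 0.059) in the 1053 genes with the highest expression and 0.43 (standard error 0.079) in the 1054 with the lowest. Genomic DNA in the libraries would add most to weakly expressed genes. By the rule set beforehand, a slope that held up in highly expressed genes would count against such DNA as the source. It held up by that rule, but it was smaller than in weakly expressed genes, the direction such DNA would give. The test therefore cannot tell. Genomic DNA stays open as a source, and the 2 slopes were not tested against each other. A candidate explanation is that treated cells held more copies of genes near the replication origin, relative to the terminus, than control cells did. The slopes of 0.48 and 0.25 in the 2 parts of the order do not exclude it, but they restate the gradient and are no evidence for it. It assumes that the tags start at the origin, and a difference in growth phase between the cultures was not tested.

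The run of 34 neighbouring genes also invites a second look. Chance placement is argued against, since the longest run over 10000 placements was 3. Those placements treat neighbouring genes as independent, so they speak to clustering only. The lower of the 2 treated libraries had a median log2 ratio of 3.93 to the control mean over the run. That ratio cannot decide whether a single treated library was its source, since the genes were chosen by a test that favours agreement of both. A hypothesis left open is that the run may be the R- and F-type pyocin cluster, phage-tail-like bacteriocins whose genes are known to respond to DNA damage. The list fixed in advance defined this cluster as the genes between trpE and trpG, and 37 genes, prtN, prtR and ptrB among them, lie there in PAO1, beside 34 in the run and 36 when 1 uncalled gene is bridged. Size alone does not identify the run, so its genes are not named.

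All called genes rose in the fit without a replicate term, but some other fits, the one with that term among them, called falls. Once the 8 most abundant features were removed before scaling, 58 genes were higher and 0 lower, so the calls did not rest on these features. A trimmed mean gives such extreme features little weight in any case. The removal therefore speaks to no other distortion of the scaling. In simulations that gave both groups the same spread, the test recovered 93.2% of 8-fold falls and 88.8% of 8-fold rises. It was therefore not blind to falls in itself. These simulations cannot say whether a wider spread in one group hid falls. Spread between libraries stays open: the fit with a replicate term kept all 4 libraries and called 52 genes lower, but the labels do not pair the samples. The fits with a single control library (25 genes lower without control replicate 2, 0 without control replicate 1) do not decide it, and a biological lack of falls was not tested.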
